A study of Mus musculus with 29 samples.

How the data were processed

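Livers of mice given the carcinogen diethylnitrosamine (DEN) were profiled by RNA sequencing in 29 libraries. They fall into 8 groups by tissue (tumour or non-tumour liver), treatment (HFD or HFD_alcohol in the labels) and genotype (labelled IL17RA-/- or WT). The groups hold 5, 5, 3, 3, 4, 3, 3 and 3 libraries. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says which libraries came from the same animal, so p-values measure the spread between these libraries. The series text speaks of liquid ethanol feeding or pair-feeding, whereas the sample labels say HFD and HFD_alcohol; the sample labels were used.

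RNA was isolated with a silica column kit and polyA-selected stranded libraries were made, per the labels' protocols. STAR 2.5.1a, RSEM 1.3.0 and build GRCm38 are named in the submitters' processing notes, without their order; the annotation and any filter are not given in the sources used here. The authors deposited 1 table of CPM, counts scaled to a common total over the genes listed, with 22187 gene IDs. Each column of the deposited CPM has the same sum. In each library the nonzero values were multiples of a step that stood for 1 count; 83.1% to 86.0% of them were whole counts within a tolerance of 0.002 counts, and the rest were whole hundredths of a count, as RSEM writes expected counts. The recovered depth was 3213696 to 9660583 counts per library, so 3 counts, taken as the floor, stood for 0.31 to 0.93 CPM. This floor covers counting error only. Symbols and coordinates came from GENCODE M21 (GRCm38): 21653 IDs had a symbol and 534 had none, and the latter held 0.14% of the counts. No mitochondrially encoded or Y-linked gene was listed, so checks that need them were not made.

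Tests used limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trend in the variance. Genes at 1 CPM or more in at least 3 libraries of the fit were tested, and a Benjamini-Hochberg adjusted p under 0.05, two-sided, counted as a call. Fold changes are on the log2(CPM + 1) scale, which understates the change of low genes. Comparisons within non-tumour liver were fitted on its 16 libraries, those within tumour on its 13 libraries, and those between tissues on all 29. The 12 two-group comparisons, the 3 interactions, 39 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. A comparison of all tumour with all non-tumour libraries was added after seeing the data.

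Of the 39 lists, 34 had 3 or more tested members. They were tested with camera at a preset correlation between genes of 0.01, and again with an estimated correlation. At the preset correlation 7 to 21 lists passed per comparison. With an estimated correlation 0 passed in any of the 16 comparisons with all libraries, and 2 passed in 1 comparison when doubted libraries were left out. List results are therefore given as descriptions of these libraries. Counts "adjusted over the list alone" use the list's members as the family.

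The named genes were Il17ra in comparisons of genotype; up to 5 genes with the largest rise and 5 with the largest fall among called genes with a mean of 5 CPM or more in the higher group and no overlap between groups, leaving out predicted genes; and 2 members of each of up to 8 lists with a called member. Up to 2 genes each way were named in the other comparisons. Members of 3 lists (IL-17-responsive genes, cholesterol synthesis and Kupffer cell markers) were named in comparisons of genotype whether or not they passed. The fuller rule was applied to tumours on HFD after their calls were seen, and 5 genes near Il17ra were named after their values were seen. Some genes that the rule names are not reported here.

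Replicate numbers were checked as possible pairs through the correlation of deviations from group means. For alcohol against HFD in non-tumour WT liver the 3 pairs correlated at 0.34, 0.27 and 0.13, and all 3 correlated best with their own number. The numbers may therefore pair the libraries in that comparison, but the labels state no pairing and it is uncertain. The results given for that comparison come from the fit without pairing. By chi-square per gene, HFD replicate 1 lay nearest alcohol replicate 1 (26.3) among the WT alcohol libraries. HFD replicate 2 lay nearer alcohol replicate 5 (7.7) than 2 (14.6), and HFD replicate 3 nearer alcohol replicate 1 (29.1) than 3 (39.9). A fit with the number as a block again called 0 genes in that comparison.

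Alternatives were a pseudocount of 0.1, no filter, median-ratio rescaling, other sets of libraries in the fit, a replicate block and leaving out each library. Limma-voom on the recovered expected counts was chosen after seeing the data, as were 2 fits with fewer libraries. One leaves out 4 libraries doubted on inspection, by no set criterion: WT HFD tumour replicate 4, labelled alcohol tumour replicate 5, labelled HFD non-tumour replicate 3 and WT HFD non-tumour replicate 1. The other leaves out labelled non-tumour alcohol replicates 2 and 4, which lay farthest from the rest on the first component of non-tumour liver. Other splits of the same libraries were counted, at most 100 per comparison. The closest pair of libraries differed by a chi-square per gene of 7.7, where counting noise gives 1, so no library was taken as a duplicate.

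The fits were tested on simulated data with 200 changed genes per comparison, drawn from the real means, depths and residual spreads. For genotype in non-tumour alcohol liver (12668 genes), 68.0% of genes changed 2-fold and 91.8% of those changed 4-fold were recovered, with 9 unchanged genes called. For genotype in tumours on alcohol (13133 genes) the shares were 34.7% and 85.4%, with 3 unchanged genes called. Over the 12 two-group comparisons they ran from 29.6% (diet in WT tumours, 13123 genes) to 68.0% and from 69.0% (diet in labelled tumours, 13116 genes) to 91.8%. In the interactions they were 26.5% and 70.7% by diet in non-tumour liver (12668 genes), 11.3% and 47.0% by diet in tumours (13137 genes) and 39.2% and 70.0% by tissue on alcohol (13300 genes). Simulated genes vary independently, unlike real ones. The residual spreads already hold counting noise and counts were drawn on top of them, so this noise enters more than once. The shares recovered are therefore approximate, most of all for low genes. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.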

Results

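Gene expression was measured in tumour and non-tumour liver of mice injected with 25 mg/kg DEN, a liver carcinogen, at 2 weeks of age and then fed for 18 weeks. The design crosses tissue, diet (HFD or HFD_alcohol, called alcohol here) and the genotype label for the IL-17 receptor A, the receptor subunit through which IL-17A signals. Non-tumour liver had 5 libraries labelled IL17RA-/- and 5 WT libraries on alcohol, and 3 of each on HFD. Tumours had 4 and 3 on alcohol and 3 and 3 on HFD. Recovered depth was 4653421 to 9660583 counts in non-tumour and 3213696 to 9169115 in tumour libraries. The 10 most abundant genes held 14.6% to 19.6% of counts in non-tumour and 16.6% to 32.2% in tumour libraries.

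Il17ra (ENSMUSG00000002897, chromosome 6, 120463247 to 120487559, GRCm38) was not called lower in the libraries labelled IL17RA-/-. Its means there were slightly lower than in WT in non-tumour liver and higher in tumours. In non-tumour alcohol liver it was 26.1 ± 8.39 CPM (SD, n = 5) in these and 27.5 ± 10.2 (n = 5) in WT, and in non-tumour HFD liver 24.5 ± 10.3 (n = 3) and 26.3 ± 1.02 (n = 3). In tumours it was 50.4 ± 6.33 (n = 4) against 33.2 ± 0.753 (n = 3) on alcohol, and 59.4 ± 4.45 (n = 3) against 32.8 ± 13.8 (n = 3) on HFD. None of these 4 differences passed limma; the smallest adjusted p was 0.0562, in tumours on HFD. The sources used here do not say which exons were removed, and a value per gene cannot show the loss of a part of the transcript. The genotype is therefore given as labelled, and every direction between genotypes rests on that label.

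**Figure D1:**
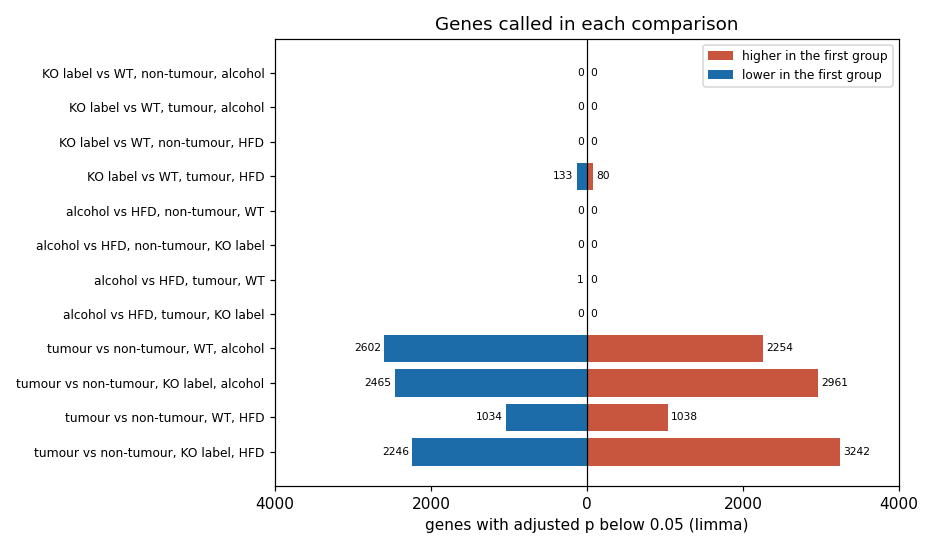
Genes with an adjusted p below 0.05 in the 12 two-group comparisons, split into those higher (right) and lower (left) in the first group named; KO label stands for libraries labelled IL17RA-/-. Tumour against non-tumour gave 2072 to 5488 genes, and genotype or diet gave 0 or 1 gene except in tumours on HFD, with 213.

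In non-tumour alcohol liver, the cholesterol synthesis genes were higher in libraries labelled IL17RA-/- than in WT as a group: all 25 had a positive log2 fold change, with a median of 0.93. Hmgcs1, which makes HMG-CoA, was at 358 ± 235 CPM (n = 5) against 135 ± 16 (n = 5), and Pmvk, phosphomevalonate kinase, at 28.3 ± 18.7 against 10.7 ± 1.84. Fatty acid synthesis genes had a median of 0.37, with 17 of 23 positive. Kupffer cell markers, genes of resident liver macrophages, were negative in 15 of 15 with a median of -0.59; Fcna was at 38.9 ± 12.9 against 57.6 ± 9.74 CPM and Vsig4 at 45.3 ± 30.8 against 64.6 ± 10.4. Fatty acid oxidation genes had a median of -0.2. In the IL-17-responsive list Mmp9 was at 0.66 ± 0.413 against 1.5 ± 0.428 CPM and Ccl2 at 2.64 ± 2.65 against 4.26 ± 2.75, with a list median of -0.16. Limma called 0 of 12829 genes, with 330 at an unadjusted p under 0.05 where chance gives 641. Limma-voom also called 0, with 324. Over the cholesterol list alone, 19 members passed ("adjusted over the list alone").

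The camera test at its preset correlation gave the cholesterol list an adjusted p of 6e-30, which became adjusted p = 0.271 with an estimated correlation. For Kupffer cell markers the values were 1.08e-09 and adjusted p = 0.434 with an estimated correlation. For fatty acid synthesis they were 1.24e-06 and adjusted p = 0.347 with an estimated correlation. For fatty acid oxidation they were 1.72e-10 and adjusted p = 0.434 with an estimated correlation. For IL-17-responsive genes they were 0.0195 and adjusted p = 0.717 with an estimated correlation. The cholesterol value per library was 6.00 ± 0.90 (mean log2, n = 5) in the labelled libraries and 5.02 ± 0.12 (n = 5) in WT, with an exact permutation p of 0.00794, the smallest that 252 assignments allow. Adjusted over the 34 lists it was 0.27, the lowest value a lone list can reach with 252 assignments, so this adjustment could not have passed. Replicates 2 and 4 of the labelled group were highest, at 7.12 and 6.75, and the lowest of that group was at 5.14. The same replicates were lowest for some Kupffer markers, with Vsig4 at 16.7 and 16 CPM and Adgre1 at 22 and 18.4, against 38.7 to 79.2 and 69.9 to 105 in the other 3 labelled libraries. This did not hold for Fcna, at 37 in replicate 2 against 29.7 in replicate 1, or for Cd163, at 31 against 19 in replicate 5. They lay farthest out on the first component of non-tumour liver. Without both, the cholesterol median was 0.36 (preset p 0.000378, adjusted p = 0.696 with an estimated correlation) and the fatty acid oxidation median -0.1, while the fatty acid synthesis median stayed about as large (0.34 against 0.37), although with fewer libraries its call was lost (p 0.0637). The Kupffer and IL-17-responsive medians then turned to 0.18 and 0.14, with preset p-values of 0.639 and 0.981. The Kupffer median was -0.36 and -0.32 without labelled replicate 2 or 4, and the fatty acid oxidation median -0.11 without replicate 2. The IL-17-responsive median ran from -0.32 to -0.04 leaving out 1 library, and its call was lost without labelled replicate 2 or 4 (medians -0.09 and -0.08) or WT replicate 1 or 4 (-0.04 and -0.14), with preset p-values up to 0.215.

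**Figure D2:**
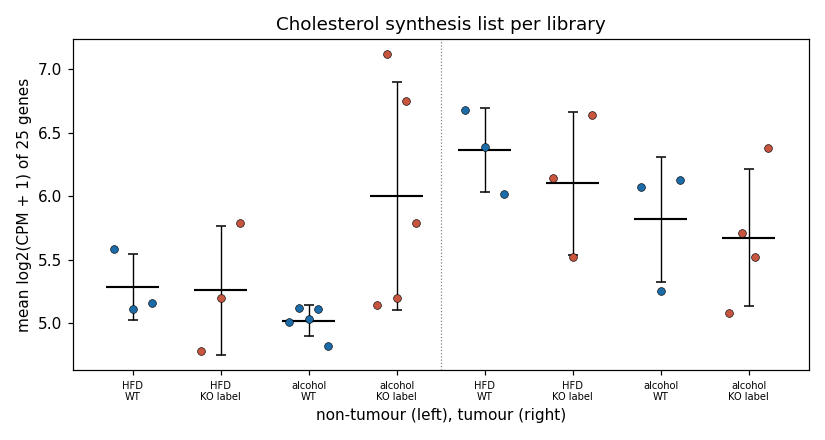
Mean log2(CPM + 1) over the 25 cholesterol synthesis genes in each library, by group; horizontal lines are group means and bars are 1 SD, and KO label stands for libraries labelled IL17RA-/-. The 5 non-tumour alcohol libraries with that label run from 5.14 to 7.12, above the 5 WT libraries at 4.82 to 5.12.

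In tumours on alcohol, 20 of 20 pericentral genes, which depend on Wnt signalling near the central vein, had a positive log2 fold change in libraries labelled IL17RA-/-, with a median of 1.05. Cholangiocyte and progenitor markers had a median of 0.64 with 13 of 15 positive, and alcohol and drug metabolism genes 0.39 with 25 of 28. Cholesterol synthesis had a median of -0.11, with Sc5d at 287 ± 57.9 CPM (n = 4) against 372 ± 121 (n = 3) and Mvk at 11.7 ± 1.62 against 15.1 ± 3.97. Kupffer cell markers had a median of 0.17, with Fcna at 13.6 ± 4.18 against 8.18 ± 4.73 and Clec4f at 46.4 ± 13.6 against 29.3 ± 15.2. IL-17-responsive genes had a median of 0.01; Ccl20 was at 2.84 ± 4.78 against 0.289 ± 0.128 and S100a9 at 0.889 ± 0.338 against 2.03 ± 1.79.

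Limma called 0 of 13269 genes in this comparison, with 261 at an unadjusted p under 0.05, and limma-voom called 0, with 202. The preset camera p was 8.26e-09 for pericentral genes, against adjusted p = 0.838 with an estimated correlation. For cholangiocyte markers and drug metabolism it was 0.000494 and 0.000993, each with adjusted p = 0.838 with an estimated correlation. It was 0.000947 for cholesterol synthesis (adjusted p = 0.926 with an estimated correlation); Kupffer cell markers, at 0.243, and IL-17-responsive genes, at 0.403, did not pass. The pericentral median was 0.63 without labelled replicate 5 and 0.55 without WT replicate 4. Without labelled replicate 7 the cholangiocyte median was 0.36 and that of drug metabolism 0.25, and without WT replicate 4 the cholangiocyte median was 0.32. The cholesterol median ran from -0.4 to 0.1, and its call was lost without labelled replicate 4 (0.1) or WT replicate 4 or 6 (-0.01 and 0).

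The 5 genes given next lie on chromosome 6 near Il17ra and were chosen after their values were seen. Mug2, a protease inhibitor of the murinoglobulin family (122006761 to 122085965), was at 99.5 ± 80.8 CPM (n = 4) in alcohol tumours labelled IL17RA-/- and 1520 ± 397 (n = 3) in WT, an adjusted p of 0.0872. In HFD tumours it fell to 63.2 ± 31.4 (n = 3) from 1820 ± 711 (n = 3), a log2 fold change of -4.86 ± 0.65 (SE) and adjusted p of 0.0147. Klrb1b, a natural killer cell receptor (128813706 to 128826331), was at 0.232 ± 0.104 against 65.2 ± 23.8 CPM on alcohol and 0.139 ± 0.24 against 67.9 ± 58.1 on HFD, where 1 WT tumour was at 0.928 and the adjusted p was 0.0509. Adipor2, an adiponectin receptor (119353150 to 119417704), was at 165 ± 10.6 against 272 ± 27.7 CPM on alcohol (adjusted p 0.301) and fell on HFD to 159 ± 14.7 from 386 ± 38.6, an adjusted p of 0.00368. Atp6v1e1, a proton pump subunit, fell on HFD to 48.2 ± 3.62 from 99.6 ± 18.1 (adjusted p 0.0315) and was at 53.9 ± 4.41 against 85 ± 13.9 on alcohol. Apobec1, an RNA-editing enzyme, was at 41.8 ± 7.39 against 18.5 ± 7.74 on alcohol and 40.7 ± 10 against 29.9 ± 4.05 on HFD, and passed in neither. In non-tumour liver Mug2 did not follow the label: of 8 labelled libraries 3 were at or above the lowest WT tumour and 4 at or below the highest labelled tumour, and of 8 WT libraries 4 and 4.

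**Figure D3:**
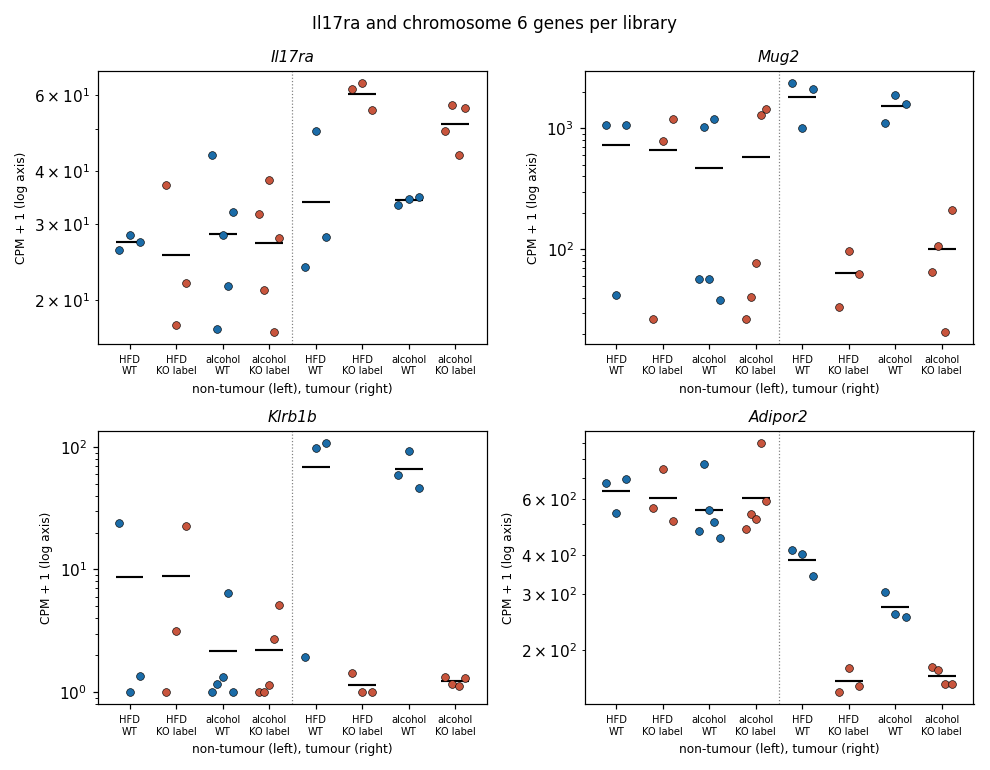
CPM + 1 on a log axis for Il17ra and 3 chromosome 6 genes in each of the 29 libraries; lines are arithmetic group means, and KO label stands for libraries labelled IL17RA-/-. In tumours Mug2 runs from 19.9 to 209 CPM in labelled and 1010 to 2350 CPM in WT libraries, whereas in non-tumour liver both labels hold low and high libraries.

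In non-tumour HFD liver, hepatocyte identity genes were slightly higher in libraries labelled IL17RA-/-, with a median of 0.21 and 23 of 26 positive, while cell cycle genes were negative in 37 of 37 (median -0.73) and interferon response genes in 27 of 27 (median -0.79). WT replicate 1 held tumour markers, with Afp at 141, Prom1 at 17.7 and Plk1 at 5.32 CPM, against 9.37 and 5.17, 4.77 and 2.25, and 1.36 and 1.57 in WT replicates 2 and 3. Of the non-tumour libraries it lay nearest the tumours on the first component of all libraries, at -13.3. Labelled replicate 3 had Afp at 155 and Gpc3 at 263 CPM. Kupffer cell markers had a median of -0.61; Slc40a1, the iron exporter, was at 197 ± 71.4 CPM (n = 3) against 289 ± 8.11 (n = 3) and Adgre1, which encodes F4/80, at 64.3 ± 10.2 against 133 ± 60.5. Of the IL-17-responsive genes (median -0.14), Tnf was at 0.291 ± 0.504 against 1.62 ± 0.935 and Il1b at 3.29 ± 2.23 against 7.48 ± 4.03. Of the cholesterol genes (median -0.02, in camera upwards), Ebp was at 121 ± 15.4 against 109 ± 21.3. Limma called 0 of 12829 genes, with 461 at an unadjusted p under 0.05, and limma-voom 0, with 492.

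The preset camera p was 1.04e-10 for hepatocyte identity (adjusted p = 0.119 with an estimated correlation). It was 1.67e-08 for cell cycle (adjusted p = 0.577 with an estimated correlation). It was 5.14e-07 for interferon response (adjusted p = 0.664 with an estimated correlation). For Kupffer markers and cholesterol synthesis it was 0.028 and 0.0228, both with adjusted p = 0.786 with an estimated correlation; IL-17-responsive genes did not pass, at 0.781. The median of all genes was -0.117 here and 0.001 after rescaling. Without WT replicate 1 the cell cycle and interferon medians were -0.45 and -0.5, and without WT replicate 3 that of hepatocyte identity was 0.13. Without WT replicate 1 and labelled replicate 3, both doubted on inspection, the medians were -0.34 for interferon response (preset p 0.13), -0.28 for Kupffer markers (0.301), -0.13 for cholesterol synthesis (0.896) and -0.37 for cell cycle. The Kupffer call was lost without labelled replicate 1 or 3 or WT replicate 1 or 3, with medians of -0.76, -0.56, -0.41 and -0.61 against -0.61 with all libraries, and the median was -0.99 without WT replicate 2. The cholesterol call was lost without labelled replicate 3 or WT replicate 2 or 3, with medians of -0.25, -0.14 and -0.13, and its median turned to 0.19 and 0.07 without labelled replicate 1 or WT replicate 1.

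In tumours on HFD, 80 genes rose and 133 fell in libraries labelled IL17RA-/-. Lars2, a mitochondrial leucyl-tRNA synthetase, rose to 577 ± 603 CPM (n = 3) from 26.8 ± 10.2 (n = 3), Igfbp2 to 451 ± 271 from 79 ± 79.8. Vmn2r3, Lrrc4 and Wnk4 rose to 14.5 ± 3.75, 14.8 ± 2.36 and 20.2 ± 3.62 from 1.87 ± 0.608, 3.72 ± 4.78 and 4.77 ± 2.22. Tubb2b fell to 0.951 ± 0.343 from 10.4 ± 6.59, AW112010 to 28.8 ± 11.3 from 92.7 ± 9.65, Ly6a to 9.89 ± 3.5 from 34.2 ± 15.1 and Clec7a, the dectin-1 receptor of myeloid cells, to 14.6 ± 4.81 from 46 ± 5.31. Of 24 genes of the NRF2 antioxidant programme, 23 were negative, with a median of -1.34; Ephx1 fell to 256 ± 18.6 from 479 ± 127, and Gclm was at 119 ± 23.1 against 252 ± 99.1 (adjusted p 0.055). The immediate early genes Zfp36 and Ier2 rose to 62.5 ± 6.67 and 21 ± 1.19 from 26.1 ± 5.65 and 11.7 ± 0.906, and the clock genes Per1 and Nr1d1 to 76.7 ± 2.14 and 78 ± 3.73 from 25.5 ± 14 and 33.5 ± 9.92. The list that holds Zfp36 and Ier2 was fixed as a sign of sample handling. Neither handling nor time of collection was tested as a source of these differences.

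In the same comparison Pck1, a gluconeogenic enzyme, rose to 1760 ± 703 CPM from 487 ± 269, the glutaminase Gls2 to 154 ± 3.69 from 60.2 ± 15.4 and the stress gene Trib3 to 91.5 ± 25.5 from 31.5 ± 11.9. The malic enzyme Me1 fell to 43.2 ± 8.17 from 141 ± 72.1, the acyltransferase Agpat2 to 54.7 ± 10.9 from 102 ± 24.8 and the fatty acid transporter Cd36 to 102 ± 12.7 from 326 ± 178. Sesn2 (31 ± 4.88 against 16.9 ± 5.37) and Fitm1 (1.42 ± 1.11 against 9.85 ± 10) did not pass. Neither did the cholesterol gene Idi1 (44.5 ± 27.1 against 84.9 ± 38.8), the IL-17-responsive genes Ccl2 (2.96 ± 1.12 against 7.71 ± 2.51) and Steap4 (219 ± 53.4 against 357 ± 120), or the Kupffer markers C1qc (54.2 ± 2.74 against 96.1 ± 17.2) and Cd68 (11.4 ± 1.1 against 20 ± 3.83). MHC class II genes had a median of -1.16 with 8 of 8 negative. Monocyte-derived macrophage markers had a median of -0.79 and T and NK cell markers one of -0.76. Adjusted over the list alone, 13 NRF2 genes fell and 1 rose, and 7 MHC class II and 6 macrophage genes fell, while 5 immediate early genes rose.

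The preset camera p was 1.35e-05 for the NRF2 list and 0.000779 for immediate early genes, both with adjusted p = 0.794 with an estimated correlation. For MHC class II, monocyte-derived macrophages, T and NK cells and the clock it was 0.00179, 0.00709, 0.0123 and 0.0149, each again with adjusted p = 0.794 with an estimated correlation. IL-17-responsive genes (median -0.43, p 0.33), cholesterol synthesis (median -0.4, p 0.722) and Kupffer markers (median -0.46, p 0.206) did not pass. The 213 calls of 13269 genes were unstable: rescaling gave 614 (415 higher and 199 lower) and fitting the compared groups alone 5. Leaving out labelled replicate 4, 5 or 6 gave 0, 1 and 0, and leaving out WT replicate 5 or 6 gave 1174 and 72. Without WT replicate 4, which lay between non-tumour liver and the other tumours, 3 genes passed. The NRF2 median was then -0.74 and that of T and NK cell markers -1.23. The IL-17-responsive list then passed camera at the preset correlation (median -0.66, p 0.0252, and adjusted p = 0.66 with an estimated correlation). The T and NK cell call was lost without labelled replicate 4 or WT replicate 5 or 6, with medians of -0.43, -0.45 and -0.73. That of macrophages was lost without WT replicate 6 and that of the clock without labelled replicate 6, with medians (-0.74 and 0.22) close to those of all libraries. The clock median (0.25) was 0.56 and 0.49 without labelled replicate 5 or WT replicate 5.

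Alcohol was compared with HFD within each genotype label in non-tumour liver. In WT, cell cycle genes were lower on alcohol in 36 of 37 (median -0.81), interferon response genes in 27 of 27 (median -0.57) and MHC class II genes in 8 of 8 (median -1.41). Alcohol and drug metabolism genes (median 0.24, 23 of 29 positive) and male-biased liver genes (median 0.64, 18 of 20 positive) were higher. In libraries labelled IL17RA-/-, cholesterol synthesis was higher on alcohol in 25 of 25 (median 0.76). There fatty acid oxidation (median -0.28, 0 of 27 positive) and lipid droplet genes (median -0.52, 1 of 18 positive) were lower. No gene passed in either: limma called 0 in WT, with 541 at an unadjusted p under 0.05, and 0 in the labelled libraries, with 745. Limma-voom called 0 and 0, with 608 and 713.

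In WT the preset camera p was 4.41e-11 for cell cycle (adjusted p = 0.42 with an estimated correlation). It was 8.81e-06 for interferon response (adjusted p = 0.723 with an estimated correlation). It was 1.62e-05 for MHC class II (adjusted p = 0.42 with an estimated correlation). It was 2.22e-09 for drug metabolism (adjusted p = 0.199 with an estimated correlation). It was 2.98e-06 for male-biased genes (adjusted p = 0.562 with an estimated correlation). In the labelled libraries it was 1.99e-08 for cholesterol synthesis (adjusted p = 0.528 with an estimated correlation). For fatty acid oxidation and lipid droplets it was 5.36e-10 and 2.4e-07, both with adjusted p = 0.419 with an estimated correlation. Without WT HFD replicate 1, which held tumour markers, the WT medians were -0.49 for cell cycle, -0.37 for interferon response, 0.12 for drug metabolism and -0.83 for MHC class II. The male-biased median was 0.38, 1.21 and 0.27 without WT alcohol replicate 2, WT HFD replicate 2 or WT HFD replicate 3. In the labelled libraries, without alcohol replicate 2 the medians were 0.4 for cholesterol, -0.15 for fatty acid oxidation and -0.25 for lipid droplets. Without HFD replicate 2 they were -0.15 for fatty acid oxidation and -0.33 for lipid droplets, and without HFD replicate 1 the cholesterol median was 0.49. Without alcohol replicates 2 and 4 together the cholesterol call was lost (median 0.17, preset p 0.518), and the medians were -0.12 for fatty acid oxidation and -0.06 for lipid droplets. Across 12829 genes, which are not independent replicates, the fold changes in the 2 genotypes correlated at r = 0.3 (rho 0.269), with no shared library.

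In tumours of WT mice, 1 gene differed between alcohol and HFD. Prdx6, a peroxiredoxin, was at 173 ± 31.9 CPM (n = 3) on alcohol against 391 ± 27.4 (n = 3) on HFD, an adjusted p of 0.0467. In labelled tumours it was at 163 to 189 CPM on HFD and 186 to 237 on alcohol, so the WT HFD tumours stood apart. The same 3 WT HFD tumours are the reference for genotype in HFD tumours, so differences seen in both comparisons are not independent. MHC class II genes were lower in 8 of 8 (median -1.51), monocyte-derived macrophage markers in 15 of 16 (median -1.13) and NRF2 genes in 22 of 24 (median -1.08), while unfolded protein response genes were higher in 18 of 24 (median 0.26). In tumours labelled IL17RA-/-, pericentral genes were higher on alcohol in 20 of 20 (median 0.85) and male-biased genes in 17 of 18 (median 0.89), and cholesterol synthesis was lower in 25 of 25 (median -0.37). There limma called 0 genes, with 293 at an unadjusted p under 0.05, and limma-voom 0, with 250.

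In WT tumours the preset camera p was 1.32e-05 for MHC class II (adjusted p = 0.632 with an estimated correlation). It was 1.32e-05 for both monocyte-derived macrophages and the unfolded protein response, each with adjusted p = 0.239 with an estimated correlation. It was 1.96e-05 for NRF2 (adjusted p = 0.686 with an estimated correlation). In labelled tumours it was 6e-10 for pericentral genes and 4.67e-07 for both male-biased genes and cholesterol synthesis, each with adjusted p = 0.778 with an estimated correlation. The Prdx6 call was lost without a filter, after rescaling, with the compared groups alone, with a block and by limma-voom, with 0 genes each, while its log2 fold change (-1.19 ± 0.16, SE) was -1.02 after rescaling and -1.19 in the others. It was -1.27 to -1.02 leaving out 1 library. Leaving out WT alcohol replicate 4 or 6 or WT HFD replicate 4 or 6 also gave 0, WT alcohol replicate 5 gave 56 and WT HFD replicate 5 gave 18. The median of all genes was -0.165 here and -0.013 after rescaling. Without HFD replicate 4, the NRF2 median in WT tumours was -0.6, and without HFD replicate 5 that of the unfolded protein response was 0.16. In labelled tumours the pericentral median was 0.5 without alcohol replicate 5 and the male-biased median 0.53 without alcohol replicate 7. The cholesterol median was -0.22, -0.59 and -0.65 without alcohol replicate 4, alcohol replicate 7 or HFD replicate 5, and its call was lost without HFD replicate 6 (median -0.15, preset p 0.0722).

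Tumours were compared with non-tumour liver. In WT mice on alcohol, 2254 rose and 2602 fell. The oncofetal genes Afp and Gpc3 rose to 263 ± 101 and 178 ± 81.7 CPM (n = 3) from 9.56 ± 11.1 and 9.24 ± 11.7 (n = 5). Igdcc4, Gldn and Klrb1b rose to 74.9 ± 16, 138 ± 35.4 and 65.2 ± 23.8 from 1.97 ± 2.08, 6.97 ± 7.6 and 1.17 ± 2.35. Cyp2e1, the ethanol-oxidising cytochrome, fell to 327 ± 171 from 7000 ± 843, Cyp27a1, a bile acid synthesis enzyme, to 54.7 ± 18.9 from 395 ± 21.6. The uptake transporter Slco1b2 fell to 109 ± 63.8 from 1900 ± 251, and the fatty acid oxidation genes Cpt2 and Acadvl to 49.1 ± 0.444 and 166 ± 3.75 from 144 ± 13.9 and 421 ± 18.9. The Kupffer genes Cd163 and Fcna fell to 1.92 ± 1.26 and 8.18 ± 4.73 from 42.3 ± 17.5 and 57.6 ± 9.74.

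**Figure D4:**
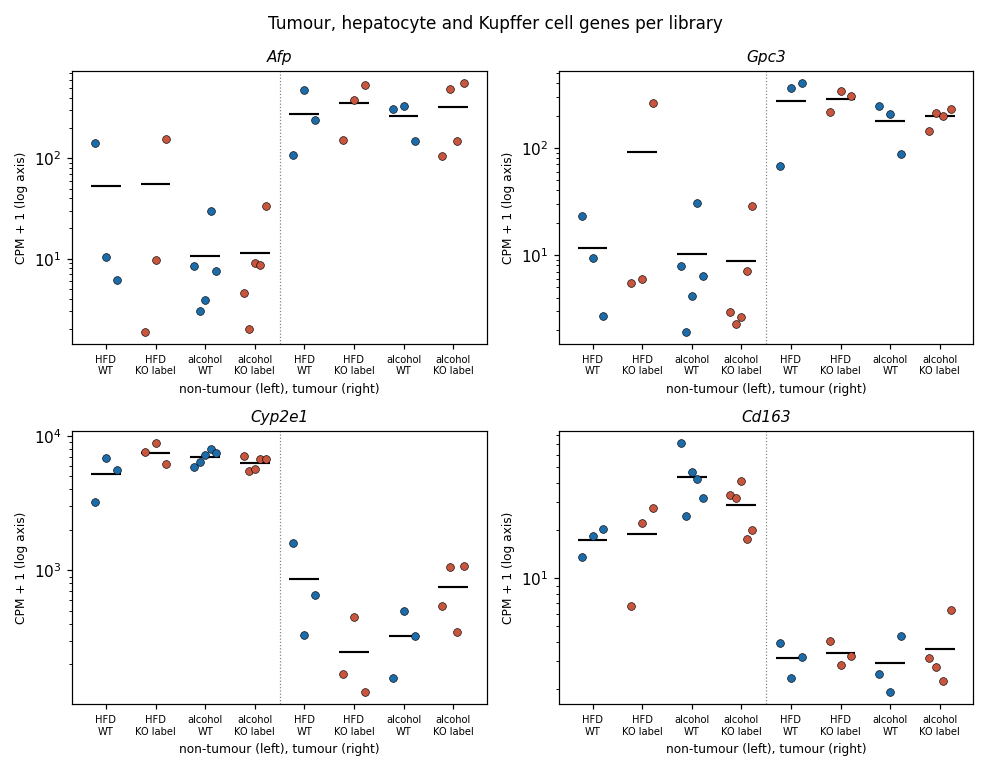
CPM + 1 on a log axis for Afp, Gpc3, Cyp2e1 and Cd163 in each of the 29 libraries; lines are arithmetic group means, and KO label stands for libraries labelled IL17RA-/-. In WT mice on alcohol Afp runs from 147 to 333 CPM in tumours and from 1.99 to 29 CPM in non-tumour liver.

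Male-biased secreted and detoxifying genes fell in the same comparison: Mup3 to 318 ± 114 CPM from 6420 ± 2050 and Cyp2d9 to 223 ± 35.6 from 1160 ± 320. Mup1, Mup7 and Mup19 fell to 1.22 ± 1.75, 52.4 ± 49.7 and 129 ± 80.9 from 137 ± 152, 3010 ± 3070 and 4340 ± 1720. Cyp2c54 and Cyp2c50 fell to 5.46 ± 3.03 and 33.7 ± 19.5 from 256 ± 29.2 and 1010 ± 147, and Ces1d to 49.5 ± 11 from 510 ± 87.8. Values within the Mup, Cyp2c, Cyp2d and Ces families are uncertain, since near-identical copies share reads and the counting could split them. Prom1, a progenitor marker, rose to 63.5 ± 38.7 from 2.33 ± 1.37, the mitotic kinase Plk1 to 8.13 ± 5.97 from 0.95 ± 0.306 and the cyclin Ccne1 to 8.99 ± 2.42 from 2.1 ± 1.62, while Mmd2, on the oncofetal list, fell to 0.351 ± 0.187 from 9.76 ± 5.87.

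By list, 16 of 18 bile acid genes fell (median -2.21), 23 of 29 drug metabolism genes (median -1.73) and 17 of 20 male-biased genes (median -3.69). A further 19 of 27 fatty acid oxidation genes (median -1.43), 16 of 21 pericentral genes (median -1.82) and 12 of 15 Kupffer markers (median -1.71) fell. Of the oncofetal list 15 of 23 rose (median 1.96) and of the cell cycle 23 of 38 (median 1.26). Of the unfolded protein response 13 of 24 rose (median 0.73) and of cholangiocyte markers 5 of 15 (median 0.4). The preset camera p was 3.65e-12 for drug metabolism (adjusted p = 0.129 with an estimated correlation). It was 3.55e-10 for bile acids (adjusted p = 0.275 with an estimated correlation). It was 9.87e-06 for the oncofetal list (adjusted p = 0.39 with an estimated correlation). It was 2.2e-05 for cell cycle (adjusted p = 0.761 with an estimated correlation). It was 0.00904 for cholangiocyte markers (adjusted p = 0.593 with an estimated correlation). For fatty acid oxidation, male-biased, pericentral, Kupffer and unfolded protein response lists it was 1.5e-09, 3.16e-09, 1.51e-07, 1.49e-06 and 0.000825, each with adjusted p = 0.39 with an estimated correlation. IL-17-responsive genes did not pass, with a median of -0.13 and a p of 0.976. The cell cycle median was 0.71 without tumour replicate 5, and the cholangiocyte median 0.68 without tumour replicate 4.

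**Figure D5:**
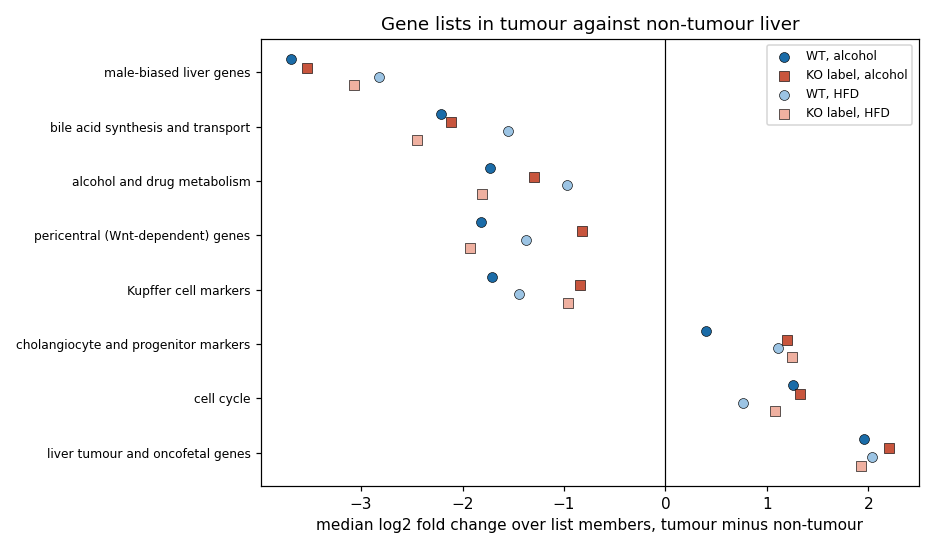
Median log2 fold change over the members of 8 gene lists, tumour minus non-tumour, in the 4 combinations of diet and genotype; KO label stands for libraries labelled IL17RA-/-. Metabolic and Kupffer lists lie below 0 and the oncofetal, cell cycle and cholangiocyte lists above 0 in all 4, with the oncofetal median between 1.93 and 2.2.

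The other tumour comparisons gave 2961 higher and 2465 lower genes in labelled mice on alcohol, 1038 and 1034 in WT mice on HFD and 3242 and 2246 in labelled mice on HFD. Cacna1b, a neuronal calcium channel, rose to 112 ± 86.1 CPM (n = 4) from 0.677 ± 0.732 (n = 5) in labelled alcohol tumours, and to 103 ± 65.6 (n = 3) from 6.09 ± 9.61 (n = 3) in labelled HFD tumours. Kif5c rose to 162 ± 63.4 from 3.72 ± 4.31 in the former and the imprinted Rtl1 to 37.6 ± 3.25 from 0.593 ± 0.652 in the latter. In WT on HFD, Slc7a11, the cystine transporter, rose to 493 ± 185 (n = 3) from 5.6 ± 4.17 (n = 3) and Gpc3 to 276 ± 182 from 10.7 ± 10.4. Mup7 and Mup19 fell on WT HFD to 14 ± 15.1 and 46.7 ± 41.2 from 1010 ± 1360 and 2350 ± 2630. On labelled HFD they fell to 7.69 ± 9.51 and 20.6 ± 25.4 from 1670 ± 2240 and 2100 ± 897. On labelled alcohol Mup7 fell to 22.2 ± 17.3 from 3480 ± 4080 and Ces3b to 7.6 ± 8.33 from 286 ± 204. In all 4 comparisons 684 genes rose and 855 fell, where independent lists would share 8.96 and 5.94. In labelled mice on alcohol 1902 rose and 2393 fell without non-tumour replicates 2 and 4. In WT on HFD the count was 413 with the compared groups alone, 1016 without tumour replicate 5, and 1060 and 1127 without non-tumour replicates 2 and 3.

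Oncofetal genes rose in 18, 11 and 17 of 23 members in labelled alcohol, WT HFD and labelled HFD tumours, and cholangiocyte markers in 11, 10 and 9 of 15. For the oncofetal list the preset p-values were 6.94e-07, 2.22e-06 and 0.000654, against adjusted p = 0.357, 0.237 and 0.558 with an estimated correlation. For cholangiocyte markers they were 5.76e-05, 1.06e-05 and 0.00172, against adjusted p = 0.432, 0.237 and 0.558 with an estimated correlation. The median of all genes was 0.151 in labelled HFD tumours and 0.051 after rescaling. Between WT and labelled mice on alcohol, which share no library, fold changes correlated across 13586 genes at r = 0.914 (rho 0.88). In both, 1917 genes rose and 2035 fell, where independent lists would share 491 and 472, and 0 were called in opposite directions by limma. With all 13 tumour and 16 non-tumour libraries, a comparison added after seeing the data, 5012 genes rose and 3654 fell. Adcy1 and Hid1 rose to 50.3 ± 20.9 and 56.1 ± 18.9 CPM (n = 13) from 3.03 ± 3.06 and 3.41 ± 3.01 (n = 16), and Mup14 and Mup10 fell to 76.9 ± 66.8 and 180 ± 207 from 2200 ± 1410 and 3940 ± 1480.

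The interactions asked whether the genotype difference depended on diet or tissue. Limma called 0 genes for genotype by diet in non-tumour liver, 0 in tumours and 0 for genotype by tissue on alcohol, with 529, 1757 and 338 at an unadjusted p under 0.05. Limma-voom called 0 in each, with 480, 1746 and 295. In simulated data 26.5%, 11.3% and 39.2% of genes changed 2-fold were recovered in these 3 interactions, so most differences of that size were missed in the simulation. At the preset correlation 17, 14 and 10 of 34 lists passed. In the first, the fatty acid oxidation list had the smallest p, with a median of -0.29 and a preset p of 1.94e-11 (adjusted p = 0.244 with an estimated correlation). Medians of others among them were 0.87 for cholesterol synthesis and 0.91 for cell cycle in the first, 1.46 for NRF2 and 1.49 for pericentral genes in the second, and -1.01 for cholesterol synthesis, 1.04 for pericentral genes and 0.81 for Kupffer markers in the third. Their preset p-values were 1.7e-07 and 6.39e-08 (adjusted p = 0.418 with an estimated correlation for both), 1.98e-06 and 0.000219 (adjusted p = 0.721 with an estimated correlation for both), and 6.6e-26, 9.98e-09 and 3.17e-06 (adjusted p = 0.243, 0.503 and 0.503 with an estimated correlation). Without the libraries doubted on inspection the medians were 0.44 for cell cycle and -0.17 for fatty acid oxidation in the first, 0.78 for pericentral genes in the second and 0.62 for pericentral genes in the third. Without labelled non-tumour alcohol replicates 2 and 4 cholesterol synthesis in the first (0.38, preset p 0.694) and Kupffer markers in the third (0.11, preset p 0.262) lost their calls, and cholesterol synthesis in the third was at -0.48. In the first, cell cycle then grew to 1.49 (preset p 3.43e-21, adjusted p = 0.209 with an estimated correlation) and fatty acid oxidation was at -0.18. Leaving out 1 library, fatty acid oxidation in the first was at -0.14, -0.19 and -0.5 without non-tumour HFD labelled replicate 2, WT replicate 1 or WT replicate 3, and cell cycle at 0.51 without that WT replicate 1. In the third, pericentral genes were at 0.6 and Kupffer markers at 0.51 without WT tumour replicate 4, and Kupffer markers at 0.49 and 0.43 without labelled non-tumour replicate 2 or 4. The median of all genes was 0.135 in the first and 0.173 in the second interaction, and -0.003 and 0.018 after rescaling. Fold changes between genotypes in non-tumour and tumour alcohol libraries did not correlate across 12603 genes (r = -0.001, rho 0.023).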

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

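The test of chromosome 6 enrichment and its repeat without the prompting genes, the spread of the marker correlation, the other profiles in the admixture test, the tests of the lists by t and of the clock gap, the fit without labelled non-tumour alcohol replicates 2 and 4 and the comparison of all libraries were chosen only after the results were seen.

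Of 60 gaps tested within groups of 4 or 5 libraries, 5 passed Dixon's critical value, where chance passes about 1 in 20. In non-tumour WT alcohol liver, replicate 4 stood above the other 4 libraries for Klrb1b (5.37 CPM, ratio of gap to range 0.941), Afp (29 CPM, 0.798) and Gpc3 (29.8 CPM, 0.793). Gaps in Afp and Gpc3 were not tested in labelled non-tumour alcohol liver. There replicate 5 was at 32.4 and 27.8 CPM, against 0.976 to 8.02 and 1.26 to 6.04 in the others. Ccl20 was at 9.96 CPM in labelled alcohol tumour replicate 7, the shallowest library (ratio 0.874), and Kif5c at 11.2 CPM in labelled non-tumour alcohol replicate 5 (ratio 0.768). Between groups, 17, 14 and 10 of 34 lists differed in the interactions at the preset correlation. Medians of those described here were -0.29, 0.87 and 0.91 for fatty acid oxidation, cholesterol synthesis and cell cycle by diet in non-tumour liver, 1.46 and 1.49 for NRF2 and pericentral genes by diet in tumours, and -1.01, 1.04 and 0.81 for cholesterol synthesis, pericentral genes and Kupffer markers by tissue; none passed with an estimated correlation.

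Mug2 and Klrb1b followed the genotype label in tumours and not in non-tumour liver, where Klrb1b went with Mug2 whatever the label: it was above 1 CPM in 6 of the 8 libraries with Mug2 at 776 to 1450 CPM and at 0.316 CPM or less in the 8 with Mug2 at 25.4 to 75.9 CPM. A total of 45 of 12963 genes did not overlap between the 7 labelled and 6 WT tumours, where chance gives 0.12% or 15 genes. In non-tumour liver, with 8 labelled and 8 WT libraries, the count was 0. Chance gives fewer genes there than in tumours, and its value was not worked out, so the 2 counts are not directly comparable. Of these 45, 5 lay within 10 Mb of Il17ra among 168 tested there (one-sided Fisher exact p 0.000277), but 4 of the 5 had prompted the test, and without the prompting genes 1 of 41 was left (p 0.405), so flanking strain sequence carried with the targeted locus stays open. Mislabelled non-tumour libraries could give the joint movement of Mug2 and Klrb1b. The other nearby markers, Atp6v1e1 and Adipor2, were tested against each other only, not against Mug2. They came out at the 37.9th percentile of random sets, with a correlation of 0.06 (jackknife SE 0.28) against a median of 0.19. This is too wide to decide, and Tmem121b was left out for its low level (at most 1.22 CPM). It was at 0.16 to 1.22 CPM in the 8 libraries with low Mug2 and at 0 to 0.141 CPM in the 8 with high Mug2. Labelled tumours (0.374 to 2.14 CPM) and WT tumours (0 to 0.155 CPM) differed in the same direction. These non-tumour values are of few counts (the floor there is 0.31 to 0.64 CPM), and the split was not tested. In the libraries with high Mug2, Adipor2 was at 506 to 896 CPM, Atp6v1e1 at 69.6 to 107 and Il17ra at 15.9 to 26.9. In those with low Mug2 they were at 451 to 560, 58.7 to 92.3 and 20.1 to 42.5. These ranges overlap but lean as between WT and labelled tumours, which was not tested. A linked variant that follows the label would not by itself give low and high Mug2 under both labels in non-tumour liver. The linked variant and mislabelling are therefore not rivals, and with so few markers neither is settled. If non-tumour labels were mixed, every comparison of genotype in non-tumour liver would rest on mixed groups. No sample was regrouped. An effect of genotype restricted to tumours would not by itself give Mug2 at 25.4 to 75.9 CPM in 8 non-tumour libraries and 776 to 1450 CPM in 8. Both labels held low and high libraries. These values argue against such an effect as the whole account of Mug2, and as a part of it the effect stays open and untested.

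The cholesterol synthesis list separated the labelled from the WT non-tumour alcohol libraries, but 34 lists were tested. In a share of 0.468 of the 252 assignments of the 10 libraries the largest absolute t of any list was at least the 2.42 of this list, so picking a list by chance is not excluded. By this statistic fatty acid synthesis separated the groups more strongly, with an absolute t of 3, reached in a share of 0.222 of the assignments. Time of day at collection was weighed through a clock gene phase, which the list value followed over 16 non-tumour libraries with group means removed (r = -0.6, permutation p 0.0137; rho = -0.58, permutation p 0.0211). This rests on the labelled alcohol libraries: over the 11 others r was -0.04 (permutation p 0.9) and rho -0.12 (permutation p 0.734), and without the 2 libraries farthest on the clock value r over the rest was -0.48. The groups had near-equal clock values, 1.87 ± 0.99 (SD, n = 5) in labelled and 1.89 ± 0.78 (n = 5) in WT, a gap of -0.01. At the slope within all groups the list difference needs a gap of -2.34 (exact permutation p 0.00794 against the gap seen), and at the steeper slope within the labelled alcohol group one of -1.18 (p 0.0873). The values argue against time of day as the source but do not exclude it at the steeper slope. Labelled replicates 2 and 4 carried much of the difference (median 0.36 without them against 0.93), and an effect of the genotype stays open.

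On the first component of all libraries (53.8% of variance) the other tumours lay at 38.1 to 69.1 and non-tumour liver at -58.3 to -13.3. Tumour WT HFD replicate 4 lay between them, at 12. Non-tumour tissue taken with it could give this. Abundant non-tumour transcripts would then imply 1 common fraction, and 34.8% of 23 such transcripts lay within 2-fold of their median of 9.3%, from -1.7% for Mup17 to 122.6% for Cyp2f2. That test assumes the mean non-tumour profile: with single non-tumour libraries as the profile the share was 26.1% to 56.5%, and without the 8 Mup transcripts, which vary widely between non-tumour libraries, 53.3%, so it does not decide. Admixture and a tumour of another differentiation state, which was not tested, cannot be told apart here.

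Splits of the same libraries were counted for each comparison. Where the real count was 0 every split reaches it by construction, which says nothing about chance: genotype in non-tumour alcohol liver (100 of 100 splits, highest other 1044), genotype in alcohol tumours (35 of 35, highest 1), diet in non-tumour WT (56 of 56, highest 2) and labelled liver (56 of 56, highest 45), diet in labelled tumours (35 of 35, highest 9) and the interactions (100 of 100 each, highest 1, 8 and 7). Counted at an unadjusted p under 0.05 instead, 65, 28, 20, 23, 17, 44, 9 and 88 of these splits, in the same order, gave as many genes as the real one, so chance was not excluded. The split with 1044 genes put labelled replicates 2 and 4 with WT replicates 2, 3 and 5, against labelled 1, 3 and 5 with WT 1 and 4; what sets these sides apart was not tested. In non-tumour WT the numbers may pair the samples, although the labels state no pairing, and splits that part such pairs were not set apart. Chance was excluded for tumour against non-tumour in WT alcohol (1 of 56, real 4856, highest other 1271), labelled alcohol (1 of 100, real 5426, highest 3620) and all libraries (1 of 100, real 8666, highest 4). With 10 splits no share under 0.05 is possible: the real and highest other counts were 0 and 0 for genotype in non-tumour HFD liver (10 splits as large), 213 and 0 for genotype in HFD tumours (1), 1 and 5 for diet in WT tumours (3), 2072 and 537 for WT HFD tumours (1) and 5488 and 0 for labelled HFD tumours (1).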

How the results depend on the processing

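Limma-voom, the fits without 4 doubted libraries or without labelled non-tumour alcohol replicates 2 and 4, and the settings of the all-library comparison were chosen only after the results were seen. Causes were not tested except where fewer libraries or genes enter by construction. Of 16 gene counts, 9 stayed within 1.5 times under every setting run, among them tumour against non-tumour in WT alcohol, labelled alcohol, labelled HFD and all libraries. With an estimated correlation 0 gene lists passed in each of the 16 comparisons with all libraries. Without the doubted libraries, drug metabolism (median -1.37) and bile acid genes (median -2.31) passed in WT HFD tumour against non-tumour. Both then had an adjusted p = 0.028 with an estimated correlation in camera. Genotype in HFD tumours (213) gave 614 after rescaling (67.6% higher against 37.6%), 5 with the compared groups alone, 62 with a replicate block, 3 without the doubted libraries, and 0 (without labelled replicate 4 or 6) to 1174 (without WT replicate 5) leaving out 1 library. Diet in WT tumours (1, Prdx6) gave 0 without a filter, after rescaling, with the compared groups alone, with the block, by limma-voom and without the doubted libraries, and 0 to 56 (without alcohol replicate 5) leaving out 1 library. WT HFD tumour against non-tumour (2072) gave 413 with the compared groups alone and 1016 (without tumour replicate 5) to 2769 leaving out 1. Genotype in alcohol tumours (0) gave 1 with the compared groups alone and 0 to 1 (labelled replicate 6 or 7) leaving out 1; diet in non-tumour WT (0) gave 0 to 2 (HFD replicate 2). The tumour diet interaction (0) gave 170 genes in a fit of all 29 libraries, with 9 lists at the preset correlation against 14, and 0 to 6 (WT HFD replicate 5) leaving out 1; the tissue interaction gave 1 with the 4 alcohol groups alone and 0 to 1 (WT tumour replicate 4) leaving out 1. Where leaving out 1 library left 2 in a group, the spread was pooled over the other groups.

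The correlation of genotype effects between tissues (-0.001) became 0.007 with a pseudocount of 0.1 and 0.01 without a filter. None of the following had been called except where said. Without labelled non-tumour alcohol replicates 2 and 4, Il17ra in non-tumour alcohol liver was at 0.25, and the Kupffer and IL-17-responsive medians there, called with all libraries, turned to 0.18 and 0.14. Leaving out 1 library, Il17ra ranged from -0.22 to 0.11 in non-tumour alcohol and from -0.47 to 0.07 in non-tumour HFD liver. The IL-17-responsive median in alcohol tumours (0.01) was 0 without a filter, -0.07 after rescaling and 0 with the compared groups alone, and -0.06 to 0.14 leaving out 1; in non-tumour HFD liver it ran from -0.5 to 0.07 and in WT alcohol tumour against non-tumour from -0.27 to 0.09. The cholesterol median in non-tumour HFD liver, called at the preset correlation, was 0.11 after rescaling and -0.25 to 0.19 leaving out 1; in alcohol tumours, also called, it ran from -0.4 to 0.1, and Kupffer markers there from -0.12 to 0.54. The replicate block changed no other count by over 1.5 times; outside diet in non-tumour WT liver the pairs did not all exceed 0.1 (lowest -0.2, highest 0.41), and in no other comparison with 3 or more pairs did every sample correlate best with its own number. No paired analysis was possible for tumour against non-tumour on HFD because the groups share no numbers; for all libraries together none was run. The planned count model was not run, since the recovered values were not nearly all whole. Depth limits genes near 0.31 to 0.93 CPM.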

Other observations

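The tests on all libraries were chosen only after the results were seen. Stellate cell and fibrosis genes, which the report does not describe, were higher in tumours over all 29 libraries: 19 of 25 rose and 2 fell, with a median of 0.86. The preset camera p was 0.0107, with adjusted p = 0.849 with an estimated correlation. Hepatocyte identity genes fell in 15 of 26 and rose in 5, with a median of -0.35 and a preset p of 0.0107 (adjusted p = 0.435 with an estimated correlation).

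Lars2 varied widely between libraries. It ran from 105 to 1420 CPM in the 7 tumours labelled IL17RA-/- and from 16.1 to 36.5 CPM in the 6 WT tumours, while in non-tumour liver WT alcohol replicates 4 and 5 were at 223 and 220 CPM and WT HFD replicate 2 at 326 CPM. Among non-tumour libraries, labelled HFD replicate 3 had Afp at 155 CPM and Gpc3 at 263 CPM, and WT HFD replicate 1 had Afp at 141 CPM.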
